A study of Mus musculus with 8 samples.

How the data were processed

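Bulk polyA RNA sequencing was analysed from 8 tumours of the mouse oral squamous carcinoma line MOC1. The series design places the tumours in the flank, while the source name is that of a tongue carcinoma, taken here as the origin of the line. Per the labels' protocols, RNA was extracted with a column kit and libraries were made with a TruSeq Stranded mRNA kit. The submitters' processing notes name bcl2fastq 2.17, cutadapt 1.18, STAR 2.7.0f and RSEM 1.3.0 with the mouse genome build mm10, without saying in which order or with which settings they were run. The deposited table holds RSEM expected counts per gene, 1 column per tumour, not scaled to library size. Between 2929 and 3179 values per column were further than 1e-06 from a whole number, and the columns summed to between 22103853 and 27258700.1. The labels do not state the gene annotation. All 55450 gene identifiers of the table were found in GENCODE release M21, which gave the symbols and the mm10 coordinates printed here.

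Each column was assigned to its tumour through the sample descriptions of the labels. The titles place 3 tumours in the control ASO arm and 5 in the Smyd3 ASO arm, and mark 2 of the 5 with R and 2 with non-R, which was read here as responder and non-responder although the labels do not spell it out. The remaining Smyd3 ASO tumour carries no response mark and was kept as a group of its own. Controls, responders and the tumour without a mark are numbered in the labels, whereas the 2 non-responders are not and are called 1 and 2 only in the order in which they are listed.

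Expected counts were rounded and analysed in R 4.3.3. Genes were kept when 2 or more libraries reached 0.424 CPM, the level that 10 reads make in the median library, and when the total was 15 reads or more. This left 16911 genes, which held 99.93% of the reads. Libraries were normalised with TMM and tested with edgeR 4.0.16 (robust quasi-likelihood fit, two-sided tests, Benjamini-Hochberg FDR threshold 0.05). Smyd3 ASO against control ASO was fitted with treatment as the only term. The other 3 contrasts, responder against non-responder, responder against control ASO and non-responder against control ASO, came from a model with 4 groups over all 8 libraries, so that the spread was shared. Responders and non-responders were defined by outcome and not by randomisation. The last 2 contrasts share their controls, so no overlap or correlation between them was read. CPM values in the text are TMM-normalised, with the SD between tumours. A fold against a group with 0 counts was computed against 3 counts over that group and is a lower bound, and a ratio to a group with 1 to 3 counts is given with its 95% counting interval. Such bounds and intervals cover counting error only. At the library totals given above, 1 CPM before TMM scaling is 22.1 to 27.3 reads, and the TMM factors were 0.9638 to 1.04.

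Before the data were examined, 33 gene lists of pathways and cell types were fixed, holding 554 genes, of which 533 were measured. Each list was tested with limma camera (limma 3.58.1) on log2 CPM with prior count 2 and a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. List members were also adjusted over the list alone. The score of a list is the mean log2 CPM of its members. Single values were compared between arms with an exact permutation test over the 56 splits of 8 tumours into 3 and 5, whose smallest two-sided p is 0.0179.

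The genes named in the text followed a rule that was also fixed beforehand. Smyd3 is named throughout. Among genes past the FDR threshold with an average log2 CPM of at least 0, complete separation of the compared libraries and a symbol that is not a predicted-gene name, the 12 with the largest positive and the 12 with the largest negative log2 fold change are named. Where fewer than 5 passed, the 5 with the smallest p that met the other conditions are named as not passing. Up to 4 members are named from each list past the camera threshold, and 2 from other lists, by smallest p. Results that need names withheld for evaluation were left out.

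The steps were tested on simulated counts for the same 16911 genes with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were drawn only from those with higher expected counts, and each gene varied independently of the others. The spread of each gene was the edgeR dispersion of these libraries, which is drawn towards a trend over all genes. The shares recovered below therefore do not hold for genes with low counts, for spread shared between genes or for genes with unusual spread. In the real data a lack of calls does not mean that changes of these sizes were absent. The Smyd3 ASO against control ASO step recovered 62% of the 2-fold and 81% of the 4-fold changes, with 8 false calls. The responder against non-responder step recovered 19% and 73% with 8 false calls, the responder against control step 20% and 80% with 11, and the non-responder against control step 35% and 84% with 6. All 5 raised lists were recovered in each comparison, and 1 of the lists that had not been raised passed in the first. These lists were drawn at random from genes that varied independently. They do not test the preset correlation where list genes move together, as in the interferon gamma list (estimated correlation 0.79). Alternatives tried were other size factors, DESeq2 1.42.0, limma voom with and without quality weights, other filters, a fold threshold, leaving out each library in turn, other library sets, a replicate block, 1 surrogate variable (sva 3.50.0) and the skeletal muscle score as a covariate. No column was left out.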

Results

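Messenger RNA was profiled in 8 flank tumours grown in C57BL/6 mice from MOC1 cells, a mouse line of oral squamous cell carcinoma. All animals received anti-PD-1, an antibody against the checkpoint receptor PD-1, over 32 days together with an antisense oligonucleotide (ASO), a short synthetic strand that binds a chosen transcript. The ASO was a control sequence in 3 animals and was directed at Smyd3, a lysine methyltransferase, in 5. Of these 5 tumours, 2 were marked R and 2 non-R, read here as responders and non-responders, and 1 carried no such mark. The control libraries held 24918685, 23282912 and 23405631 expected counts. The responders, numbered 1 and 3, held 23715284 and 27258700.1, the tumour without a mark 26022512, and the non-responders 22312339 and 22103853. Mitochondrial genes took 1.94% to 2.58% of the counts, and the 10 most abundant genes took 5.33% to 7.46%.

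The ASO target itself was measured first. Smyd3 (ENSMUSG00000055067.15, mm10 chromosome 1, 178951960 to 179518041, minus strand) stood at 11.1 ± 0.719 CPM (SD, n = 3) in control tumours and at 6.36 ± 2.40 CPM (SD, n = 5) in Smyd3 ASO tumours, 57.4% of the control mean. Every Smyd3 ASO tumour lay below every control (exact permutation test, two-sided p = 0.0357). The decrease was uneven. Smyd3 was at 39.6% of the control mean in responder 3, 41.3% in the tumour without a mark and 44.0% in non-responder 2, but at 78.4% in responder 1 and 83.6% in non-responder 1. In the edgeR fit over all genes the log2 fold change was −0.80 (SE 0.29) with an FDR of 0.246, so Smyd3 did not pass the threshold there. It was 0.11 with the skeletal muscle score as a covariate. This score overlapped neither between controls and Smyd3 ASO tumours nor between responders and non-responders, so every value with this covariate is extrapolated. The score is that of the skeletal muscle list, so the covariate removes this list's own difference by construction. Smyd1, the family member of heart and skeletal muscle, was at 0.467 ± 0.16 CPM in controls and 15.2 ± 16.3 CPM in Smyd3 ASO tumours (FDR 0.101). The bulk tissue contains host cells as well as tumour cells, and Smyd3 transcripts of both were counted.

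**Figure D1:**
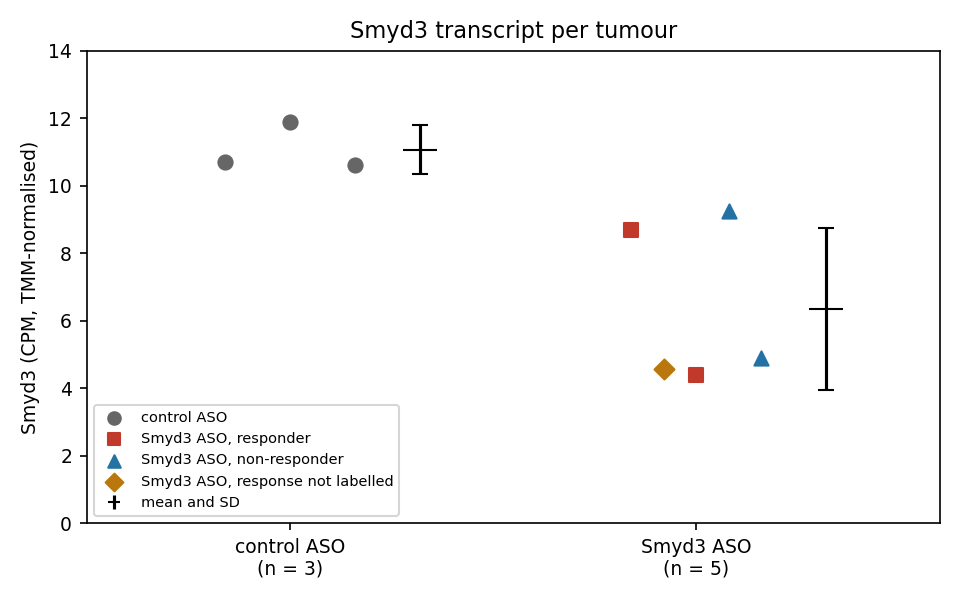
Smyd3 transcript in TMM-normalised CPM (vertical axis) for each tumour, with control ASO tumours on the left and Smyd3 ASO tumours on the right. Symbols give the response mark, and the bars beside the points give mean and SD. The 3 controls lie at 10.6 to 11.9 CPM and the 5 Smyd3 ASO tumours at 4.38 to 9.26 CPM.

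Smyd3 ASO was compared with control ASO to ask how the tumour transcriptome differs between the arms under anti-PD-1. As groups, transcripts induced by interferon gamma, transcripts of cytotoxic lymphocytes and transcripts of skeletal muscle were higher in the Smyd3 ASO tumours, and transcripts of fibroblasts and of the hypoxia response were lower, by camera with its preset correlation. None of these calls held with an estimated correlation (adjusted p = 0.452 for each), and 7 of the 56 splits of the tumours gave as many list calls as the 22 found. Of the 24 genes of the interferon gamma list, 23 lay above 0, with a median log2 fold change of 1.46. The guanosine triphosphatases Tgtp1, Igtp and Irgm2 showed log2 fold changes of 2.04 (SE 0.25), 1.90 (SE 0.27) and 1.75 (SE 0.26). Tgtp1 stood at 190 ± 9.54 CPM (n = 3) in controls and 779 ± 211 CPM (n = 5) in Smyd3 ASO tumours, and reads of Tgtp1 and its near copy Tgtp2 are hard to tell apart. In 16 of the 24 genes every Smyd3 ASO tumour exceeded every control, where 10.6% of all tested genes separated in either direction and chance would separate 3.6%. By camera, 22 of 33 lists passed the threshold, 17 of them upward and 5 downward. With an estimated correlation between genes none of the 22 passed, with adjusted p from 0.452 to 0.683. Single genes did not pass either. edgeR called 0 genes at FDR 0.05, with a lowest FDR of 0.0656, although 2630 of 16911 genes (15.6%) had an unadjusted p below 0.05. DESeq2 called 668 higher and 385 lower genes, and limma voom called 0, or 154 with sample quality weights. edgeR called 292 with the replicate block, 285 in only the 6 numbered libraries, 52 without a count filter, 25 as the mean of responders and non-responders and 23 with 1 surrogate variable. Without non-responder 1, edgeR called 249 genes, 184 higher and 65 lower, and without control 1 it called 5.

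Lists of antigen presentation and lymphocyte markers also passed camera upward, and none did with an estimated correlation. All 18 measured genes of MHC class I presentation lay above 0 with a median of 0.75, and 16 were higher when adjusted over the list alone against 0 over all genes tested. Examples were Tap1, the peptide transporter (280 ± 19.7 to 549 ± 119 CPM), and the immunoproteasome subunits Psmb9 and Psmb10 (log2 fold changes 1.15 and 1.22). The type I interferon list had a median of 1.16 and 26 of its 34 genes were higher when adjusted over the list alone. In the interferon gamma list this count was 21, in the MHC class II list 9 of 11 (median 0.85) and in the list of recruiting chemokines 8 of 17 (median 1.32), where Cxcl10 showed a log2 fold change of 2.08. Adjusted p with an estimated correlation was 0.452 for the MHC class I, type I interferon, interferon gamma and chemokine lists and 0.463 for the MHC class II list. The cytotoxic T and NK cell list had a median of 1.67, with Gzmb, Cd8a and Eomes at 2.28, 1.92 and 1.82, and 13 of its 19 genes were higher when adjusted over the list alone (adjusted p = 0.452 with an estimated correlation). The T cell list had a median of 1.35 with 0 genes adjusted over the list alone (Cd3d 1.92), and adjusted p = 0.463 with an estimated correlation. Non-responder 1 scored within the control range in the MHC class I, type I interferon, MHC class II, chemokine, cytotoxic and T cell lists. The other 4 Smyd3 ASO tumours scored above all controls in each. In the Smyd3 ASO arm the 21 skeletal muscle genes had a median of 5.82. With the muscle score as a covariate the direction turned in the type I interferon list (−0.43), the MHC class I list (−0.17), Psmb9 (−0.10) and Cd3d (−0.048). The calls were lost in the MHC class II (0.10), chemokine (0.19), T cell (0.003) and cytotoxic (0.12) lists, and the interferon gamma median fell from 1.46 to 0.77.

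Further immune lists and the proliferation list passed camera upward, and none passed with an estimated correlation (adjusted p 0.452 to 0.683). The median was 1.28 in the regulatory T cell list (Izumo1r 3.61, Foxp3 1.44), 1.13 in the checkpoint list (Cd274, which encodes PD-L1, 1.20) and 1.03 in the dendritic cell list (Ccr7 1.63). Medians were 1.95 in the B and plasma cell list (Ighm 3.97), 0.99 in the mast cell list (Hdc 1.38), 0.70 in the inflammatory cytokine list (Tnf 0.70) and 0.30 in the nucleic acid sensing list (Zbp1 1.16). The proliferation list had a median of 0.22 (Rrm2 0.58). When adjusted over the list alone, 5 dendritic cell genes were higher, 1 gene was higher in each of the regulatory T cell, checkpoint, inflammatory cytokine and nucleic acid sensing lists, and 0 in the B cell, mast cell and proliferation lists. The calls were lost for mast cells without control 1 (1.03), control 3 (0.90), responder 3 (0.49) or non-responder 2 (0.91), for proliferation without control 2 or non-responder 1 (0.087 in both), for nucleic acid sensing without control 2 (0.34) or responder 3 (0.18) and for regulatory T cells without control 3 (1.04). The muscle median of 5.82 belongs to the same tumours, and the muscle covariate turned the medians of the B and plasma cell (−1.36), mast cell (−0.15) and nucleic acid sensing (−0.49, Zbp1 −0.19) lists. It ended the calls of the regulatory T cell (0.81), checkpoint (0.026), dendritic cell (0.20), inflammatory cytokine (0.61) and proliferation (0.30) lists.

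The lists that were lower by camera, none of which passed with an estimated correlation, held matrix and oxygen-related genes among others. Among 22 fibroblast and matrix genes 18 lay below 0, with a median of −0.77, and 15 were lower when adjusted over the list alone (adjusted p = 0.452 with an estimated correlation). Pdgfrb, a receptor of fibroblasts and pericytes, went from 110 ± 27.4 to 55.1 ± 4.03 CPM, and Col6a3 from 463 ± 127 to 211 ± 34.9 CPM. All 19 hypoxia and glycolysis genes lay below 0 with a median of −0.61, and 8 were lower when adjusted over the list alone (adjusted p = 0.452 with an estimated correlation). Car9, a carbonic anhydrase induced by low oxygen, went from 46.9 ± 7.07 to 17.1 ± 5.22 CPM, and Bnip3 from 496 ± 190 to 195 ± 33.6 CPM. Smaller medians were found in the epithelial-mesenchymal transition list (−0.37, Itga5 −0.80), the TGF-beta list (−0.19, Tgfbr2 −0.43) and the basal keratinocyte list (−0.22, Pkp1 −0.62), with adjusted p of 0.485, 0.510 and 0.527 with an estimated correlation. When adjusted over the list alone, 2, 2 and 0 of their genes were lower. Without control 2 the medians of the epithelial-mesenchymal transition and TGF-beta lists were 0.05 and 0.05, and the basal keratinocyte call was lost without control 1 (−0.13) or responder 3 (−0.17). Muscle transcripts were higher in the same tumours, and with the muscle score as a covariate the medians turned to 0.13 in the hypoxia, 0.081 in the epithelial-mesenchymal transition, 0.43 in the TGF-beta and 0.83 in the basal keratinocyte list. Of the 5 genes with the smallest p that met the naming rule, none passing, 4 were Dchs1 (−1.36), Brinp3 (−1.51), Tgtp1 and Tenm4 (−1.08), each with an FDR of 0.0656.

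The largest differences were in markers of other tissues. In 20 of the 21 skeletal muscle genes every Smyd3 ASO tumour exceeded every control, and 20 were higher when adjusted over the list alone, against 0 over all genes tested. Myh1, a fast myosin heavy chain, went from 8.94 ± 4.25 to 199 ± 124 CPM, and Ckm, the muscle creatine kinase, from 0.731 ± 0.971 to 332 ± 399 CPM. The list's adjusted p was 0.452 with an estimated correlation, and it was the single list past the threshold by fry. Of 10 adipocyte genes 9 lay above 0 with a median of 5.01, and 2 were higher when adjusted over the list alone (adjusted p = 0.510 with an estimated correlation). The rise was uneven. The adipocyte score was −0.775 to −0.67 in controls, −0.185 in the tumour without a mark and 0.04 in non-responder 1. It was 1.13 in non-responder 2, 1.50 in responder 1 and 3.86 in responder 3. Plin4, which coats lipid droplets, was at 0.369 ± 0.0545 CPM in controls and 15.7 ± 23.3 CPM in Smyd3 ASO tumours. With the muscle score as a covariate 9 lists passed, 2 of them shared with the 22. Of the 22 medians 11 changed sign, among them adipocytes (−1.30) and muscle itself (−0.32). The muscle value tests nothing, since the covariate is the score of that list.

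The other 11 lists did not pass. Their medians were 0.12 in the Smyd family, 0.10 in macrophages (Cd14 0.78), 0.38 in neutrophils, −0.21 in endothelium (Flt1 −0.75), 0.54 in terminal keratinocyte differentiation, −0.08 in ERK pathway output (Dusp4 −0.81), 0.01 in DNA methylation and heterochromatin, −0.10 in immediate early and heat shock genes, 3.80 in the hair follicle, −0.37 in Schwann cells and −0.28 in erythrocytes. In the hair follicle list only non-responder 2, with a score of 5.18, lay above the highest control at 0.497. The Schwann cell list had a negative median and camera direction but a mean of 0.15, with Sox10 at 1.48 ± 2.26 CPM in controls and 31.3 ± 32.7 CPM in Smyd3 ASO tumours.

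**Figure D2:**
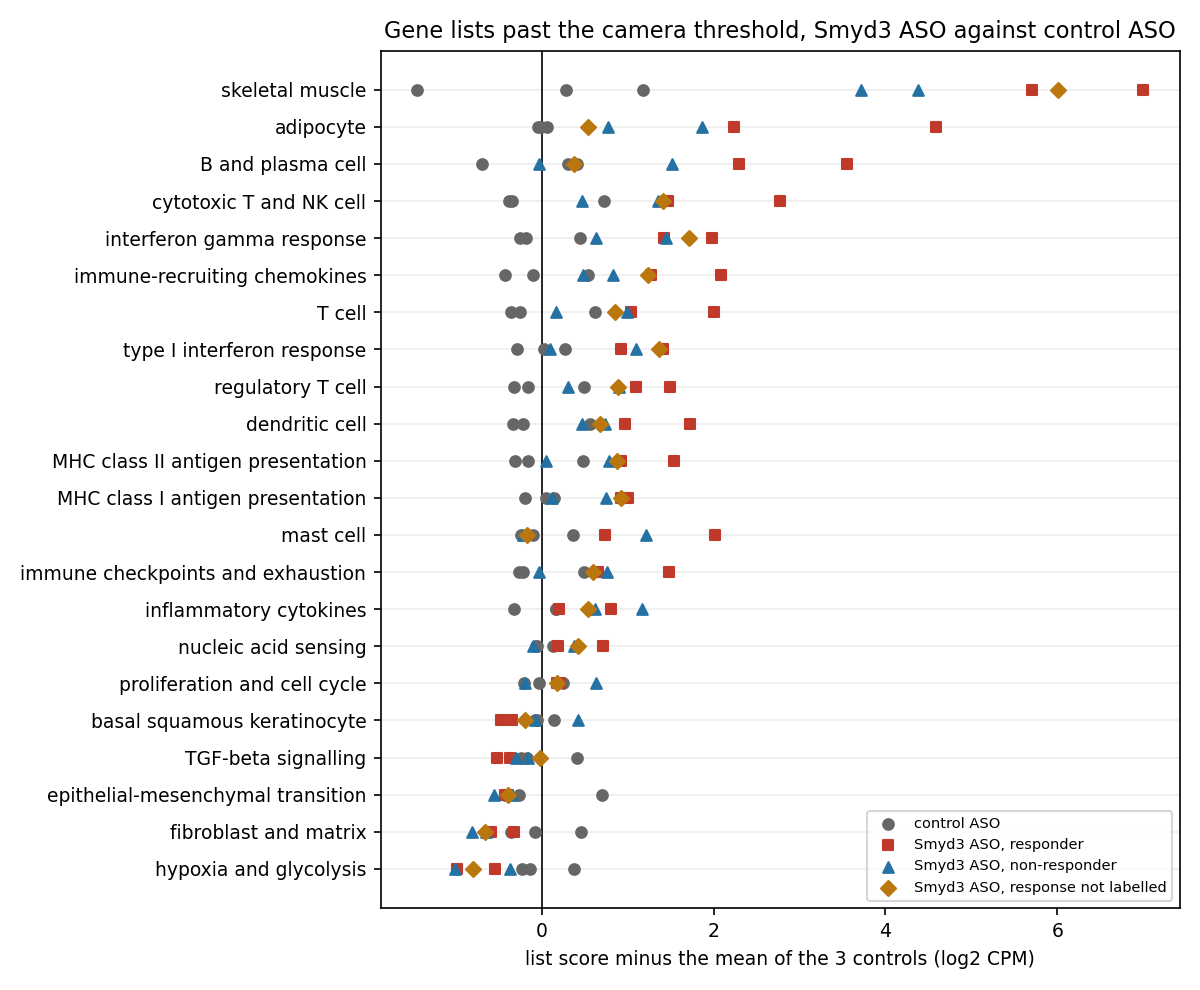
Score of each of the 22 lists past the camera threshold for Smyd3 ASO against control ASO, as mean log2 CPM of the list minus the mean of the 3 controls (horizontal axis), 1 point per tumour with symbols for arm and response mark. In the skeletal muscle, interferon gamma and inflammatory cytokine lists, among others, all 5 Smyd3 ASO tumours lie above all controls, and in the hypoxia list all 5 lie below. None of these calls held with an estimated correlation.

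Responders were compared with non-responders within the Smyd3 ASO arm. By camera with its preset correlation, lymphoid and muscle transcripts were higher in the responders as groups, and keratinocyte transcripts were lower. With an estimated correlation none of the 21 lists passed (adjusted p 0.495 to 0.520). The B and plasma cell list had all 15 genes above 0 with a median of 2.25 (Ms4a1 3.23), and the cytotoxic T and NK cell list all 19 with a median of 1.34 (Cd8b1 1.68, Nkg7 1.59). The T cell list had a median of 1.26 (Lck, a kinase of the T cell receptor, 1.46), MHC class II 0.74, MHC class I 0.48 with all 18 genes above 0 (Psme2 152 ± 24.7 to 224 ± 6.84 CPM, n = 2 each) and interferon gamma 0.65 (Irf1 0.51). The muscle list had a median of 2.90, with 16 of 21 genes higher when adjusted over the list alone, and Acta1 went from 193 ± 70.7 to 1629 ± 1465 CPM. In the muscle and the B and plasma cell lists both responders scored above both non-responders. In the interferon gamma list they overlapped, with non-responder 2 at 7.158 and responder 1 at 7.135. Non-responder 2 was also close to responder 1 in the T cell (2.74 and 2.79) and cytotoxic (1.57 and 1.69) lists. By camera 21 lists passed, 17 upward and 4 downward. The muscle covariate left 15 of the 21 calls and ended that of MHC class I (0.20) among the lists above. The muscle call also ended (0.007), which is built in, since the covariate is the score of that list.

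Epithelial genes ran the other way in this contrast, by camera but not with an estimated correlation (adjusted p 0.495). Of 23 genes of terminal keratinocyte differentiation 22 lay below 0 with a median of −1.54, and 2 were lower when adjusted over the list alone. Tgm3, a transglutaminase of the cornified envelope, was at 1.53 ± 0.528 CPM in responders and 121 ± 107 CPM in non-responders, and Krt13 at 31.3 ± 1.01 and 84.4 ± 8.08 CPM. The basal keratinocyte list had a median of −0.63 with 19 of 21 genes below 0 (Itga6 −0.94), and the heterochromatin list a median of −0.18 (Dnmt1 −0.38), which became 0.01 without non-responder 1 and did not pass without responder 1 (−0.23) or with the muscle covariate (−0.17). The hair follicle list had a median of −5.74 with 1 gene lower over the list alone. It rested on non-responder 2, since it was 1.47 without this library.

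The remaining lists that passed upward between responders and non-responders were type I interferon (median 0.49, Ifitm3 0.58), chemokines (0.79, Ccl19 3.47), checkpoints (0.59, Tox 1.35), regulatory T cells (0.66, Il10 1.41), macrophages (0.56, Adgre1 0.96), dendritic cells (0.79, Snx22 1.66), mast cells (0.87, Kit 1.19), endothelium (0.62, Cldn5 0.85), adipocytes (3.83, Cfd 4.33) and erythrocytes (1.19, Hba-a1 1.57). Non-responder 2 scored above responder 1 in the type I interferon (6.30 against 6.13), checkpoint (3.48 against 3.38), macrophage (5.64 against 5.57) and mast cell (2.61 against 2.13) lists. In the other lists just named both responders scored above both non-responders. When adjusted over the list alone, 6 adipocyte genes and 1 B cell gene were higher, and 0 in every other list that passed upward except muscle. The adjusted p of the lists lay between 0.495 and 0.520 with an estimated correlation, beside the muscle median of 2.90. Without responder 3 the calls were lost for checkpoints (0.24), regulatory T cells (0.55), macrophages (0.24), dendritic cells (0.40) and mast cells (0.017), and without responder 1 for erythrocytes (0.77). Without non-responder 1 they were lost for type I interferon (0.065), checkpoints (0.35), regulatory T cells (0.36), macrophages (0.30), mast cells (0.31) and erythrocytes (0.68). The muscle covariate turned the medians of type I interferon (−0.27) and adipocytes (−0.78, Cfd −0.74) and ended the mast cell call (0.54). Hba-a1 and Hba-a2 are near copies and their single levels are uncertain. No single gene passed. edgeR called 0 genes (lowest FDR 0.314) with 1436 genes (8.5%) at an unadjusted p below 0.05, DESeq2 called 225, 159 higher and 66 lower, and limma voom 0. The 5 genes with the smallest p, not passing, were Des, the muscle intermediate filament (53.2 ± 6.07 to 313 ± 120 CPM), Fhl1 (1.87) and Cryab (1.96), which were higher in responders, and Dlx3, a homeobox factor of keratinocyte differentiation (−1.99), and Neo1 (−0.98), which were lower. Smyd3 showed a log2 fold change of −0.12 (FDR 0.958), which became 0.29 without responder 3, 0.42 without non-responder 1 and 0.45 with the muscle score as a covariate. Without responder 1, edgeR called 22 genes.

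Responders were also set against the control arm, and here single genes passed. edgeR called 280 genes, 234 higher and 46 lower in the 2 responders than in the 3 controls (lowest FDR 0.00708). The genes with the largest increases belonged to muscle, fat and antibody-producing cells. Cox8b, a cytochrome oxidase subunit of muscle and brown fat, had 0 counts in all controls and was at least 129-fold higher in responders at 5.37 ± 3.12 CPM (FDR 0.0245). Ckm and the calcium-binding Pvalb showed log2 fold changes of 9.56 (SE 1.25) and 9.45 (SE 1.25). Ckmt2, the sarcomeric mitochondrial creatine kinase, was 691-fold higher (95% counting interval 123 to 27300), Sypl2, a triad junction protein, 611-fold (209 to 2970), and Ppp1r27 at least 94.6-fold. The adipocyte genes Cfd and Cidec were 1000-fold (342 to 4850) and 625-fold (112 to 24700) higher. The immunoglobulin genes Iglv2 and Igkv15-103 were at least 111-fold and 95.5-fold higher, Iglc2 859-fold (154 to 34000), and Ighg3 had a log2 fold change of 8.70 (SE 0.71). Reads of immunoglobulin segments are shared within their families, so the level of a single segment is uncertain.

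The 11 named genes among the 46 that were lower included chromatin and matrix genes. Srcap (ENSMUSG00000053877.12, mm10 chromosome 7, 127511983 to 127561219, plus strand), the ATPase that places the histone variant H2A.Z, went from 168 ± 33.4 to 8.28 ± 2.53 CPM, a log2 fold change of −4.34 (SE 0.31, FDR 0.0129). Srcap overlaps the annotated gene Gm42715 on the same strand. The summed level of both was 368 ± 58.0 CPM in the 3 controls and 236 ± 23.3 CPM in all 5 Smyd3 ASO tumours, a log2 ratio of −0.64. In the same tumours Srcap alone had a log2 ratio of −2.88 and Gm42715 of 0.09. Spen, a repressor that recruits histone deacetylases, had a log2 fold change of −1.31 (SE 0.20), and the corepressor Rcor2 −1.40 (SE 0.25). Lrrc15, a surface protein of matrix-producing fibroblasts, went from 174 ± 20.4 to 48.0 ± 24.5 CPM and Col12a1 from 513 ± 136 to 183 ± 13.2 CPM. The cadherin Dchs1 (−1.42), the NMDA receptor subunit Grin1 (−2.43), Tmppe (−2.09), Brinp3 (−1.64), Soga1 (−1.59) and the mitochondrial folate enzyme Aldh1l2 (−1.32) completed the named genes, with FDR of 0.0274 to 0.0460 for these 6.

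**Figure D3:**
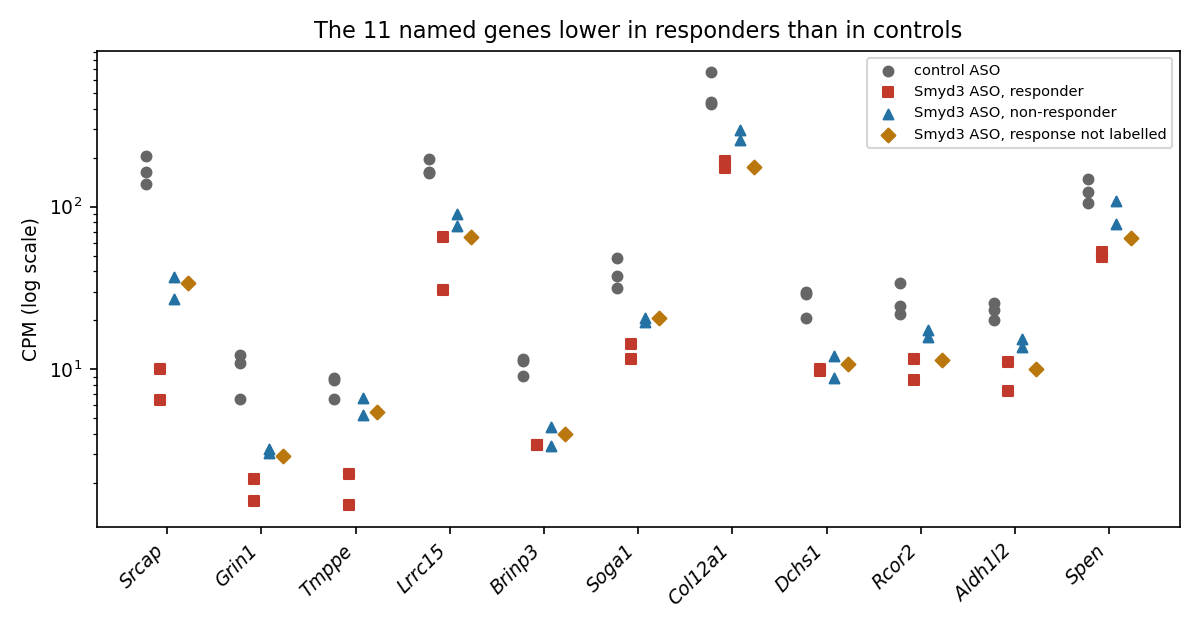
Level in CPM (vertical axis, log scale) of the 11 named genes that were lower in responders than in controls, 1 point per tumour with symbols for arm and response mark. For each gene both responders lie below all 3 controls. Srcap spans 6.49 to 204 CPM, and its reads overlap those of Gm42715.

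Within the fixed lists, 12 of the 24 interferon gamma genes rose over all genes tested, and 23 when adjusted over the list alone. The list's median was 1.70, and Igtp went from 136 ± 9.71 to 594 ± 168 CPM. The corresponding counts were 6 and 16 of 18 in MHC class I (median 0.94, Psmb10 1.49), 1 and 27 of 34 in type I interferon (1.28) and 2 and 14 of 22 in the T cell list (1.95, Cd3d 2.55). No gene passed over all genes tested in the cytotoxic list (16 of 19 over the list alone, median 2.07, Cd8a 2.45), the B and plasma cell list (11 of 15, 2.90, Ighm 4.86), the MHC class II list (9 of 11, 1.14, H2-DMa 1.37), the chemokine list (10 of 17, 1.49, Cxcl10 2.21) or the checkpoint list (7 of 13, 1.49, Lag3 1.63). In the skeletal muscle list 17 of 21 genes rose over all genes tested and 21 over the list alone, with a median of 6.52. Adipocyte genes had a median of 6.12, with 3 and 7 of 10. All of these lists passed camera, and with an estimated correlation their adjusted p lay between 0.424 and 0.452. The muscle covariate turned the medians of type I interferon (−0.71), muscle (−0.46) and adipocytes (−2.93) and ended the calls of MHC class I (0.068) and of B and plasma cells (0.998). For muscle the loss is built in, since the covariate is the score of that list.

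Of the other lists, regulatory T cells (1.63, Foxp3 2.03), dendritic cells (1.49, Flt3 2.18), mast cells (1.52, Fcer1a 2.04), macrophages (0.36, Cd14 0.87) and nucleic acid sensing (0.51, Zbp1 1.25) passed upward between responders and controls. Fibroblast (−0.81, Tagln −1.16), basal keratinocyte (−0.56, Dsp −0.79), hypoxia (−0.65, Vegfa −1.60), epithelial-mesenchymal transition (−0.52, Itga5 −0.92) and TGF-beta (−0.38, Tgfbr1 −0.58) passed downward. Without responder 3 the macrophage median was −0.052, and the nucleic acid sensing (0.077) and mast cell (0.69) calls were lost. The macrophage call was also lost without control 1 (0.23), that of nucleic acid sensing without control 2 (0.46) and that of epithelial-mesenchymal transition without control 2 (−0.13) or responder 1 (−0.49). The muscle covariate turned the medians of the fibroblast (0.41), hypoxia (1.17), epithelial-mesenchymal transition (1.29), TGF-beta (0.74) and nucleic acid sensing (−0.73) lists and ended the macrophage (0.97), mast cell (0.91) and basal keratinocyte (−0.12) calls. Over the list alone 7 dendritic cell, 4 regulatory T cell, 1 macrophage and 1 nucleic acid sensing gene were higher, and 2 hypoxia genes lower. Over all genes tested these counts were 1, 1, 1, 0 and 0. The adjusted p of the lists lay between 0.424 and 0.646 with an estimated correlation, beside the muscle median of 6.52. Pkp1 and Col12a1 fell over all genes tested, as did no other measured gene of the basal keratinocyte and fibroblast lists, in which 7 and 11 genes were lower over the list alone. The endothelial list had a median of 0.05 and a mean of 0.01, with a downward camera direction that did not pass. The count of 280 genes changed when single libraries were left out, also non-responders, which enter this contrast mainly through the shared spread. It was 0 without control 1, 78 without control 2, 6 without control 3, 36 without responder 3, 171 without non-responder 1 and 134 without non-responder 2, and it was 77 by limma voom, 1153 by DESeq2 (755 higher, 398 lower), 499 without a count filter, 171 with only the compared libraries in the fit and 0 with the muscle score as a covariate, where 8 list medians changed sign.

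Non-responders were compared with the same controls. By camera with its preset correlation, interferon gamma and muscle genes were higher and fibroblast, endothelial and hypoxia genes lower as groups. None of these lists passed with an estimated correlation (adjusted p = 0.647 for each), and the hypoxia call was lost without non-responder 2. The interferon gamma list had 23 of 24 genes above 0 with a median of 1.05, and 17 were higher when adjusted over the list alone (Tgtp1 1.67, Gbp6 1.40). The MHC class I list had a median of 0.43 with 6 genes over the list alone (Erap1, an aminopeptidase that trims peptides, 63.2 ± 5.23 to 88.0 ± 8.56 CPM), the type I interferon list 0.73 and the cytotoxic list 0.85 (Gzmb 1.54), each with 0. All 22 fibroblast genes lay below 0 with a median of −0.79 and 15 over the list alone (Col6a1 −1.13), all 16 endothelial genes with a median of −0.53 and 0 over the list alone (Flt1 −1.04), and 18 of 19 hypoxia genes with a median of −0.65 (Aldoa −0.65). The muscle list had a median of 3.72 with 19 of 21 genes over the list alone (Tnnc2 4.46). The MHC class I, type I interferon and cytotoxic lists also had an adjusted p of 0.647 with an estimated correlation. Without non-responder 2 the MHC class I (0.078), type I interferon (0.13), cytotoxic (0.37) and hypoxia (−0.36) calls were lost. The muscle covariate turned the medians of type I interferon (−0.60), MHC class I (−0.11), hypoxia (0.56) and muscle (−0.26) and ended the fibroblast (−0.12) and endothelial (−0.003) calls. The change in muscle is built in, since the covariate is the score of that list.

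Keratinocyte differentiation genes were higher in non-responders than in controls by camera, though not with an estimated correlation. The terminal differentiation list had a median of 0.97 with 18 of 23 genes above 0 and 4 over the list alone, among them Tgm3 at 0.757 ± 0.513 CPM in controls and 121 ± 107 CPM in non-responders, and Krt13 at 29.4 ± 12.2 and 84.4 ± 8.08 CPM (adjusted p = 0.647 with an estimated correlation). It did not pass without non-responder 1 (0.16). The basal keratinocyte list did not pass, with a median of −0.03, a mean of 0.17 and a downward direction. The hair follicle list had a median of 5.06 (Tchh 1.99, adjusted p = 0.647 with an estimated correlation), which became −1.91 without non-responder 2. Other lists that passed were MHC class II (0.45, H2-DMb1 0.56), chemokines (0.63, Ccl2 1.45), T cells (0.72, Tcf7 0.81), neutrophils (0.61, Clec4e 0.96), dendritic cells (0.30, Xcr1 1.02), inflammatory cytokines (0.53, Ptgs2 1.90), proliferation (0.24, Rrm2 0.71, turning to −0.21 without non-responder 1), adipocytes (2.29, Plin4 2.79) and, downward, epithelial-mesenchymal transition (−0.59, Prrx1 −0.62). Their adjusted p lay between 0.647 and 0.712 with an estimated correlation, beside the muscle median of 3.72. Without non-responder 2 the calls were lost for MHC class II (0.002), chemokines (0.41), T cells (0.059), neutrophils (0.56), dendritic cells (0.13), adipocytes (1.01) and epithelial-mesenchymal transition (−0.64). They were also lost for MHC class II without control 1 (0.37) or control 3 (0.23), chemokines without control 1 (0.46), neutrophils without control 2 (0.34), proliferation without control 2 (0.13) or control 3 (0.22) and epithelial-mesenchymal transition without control 2 (−0.069). The muscle covariate turned the medians of terminal differentiation (−0.15), neutrophils (−0.95), inflammatory cytokines (−0.12), adipocytes (−2.15), hair follicle (−0.36) and epithelial-mesenchymal transition (0.77) and ended the proliferation call (0.22). By camera 19 lists passed, 15 upward and 4 downward, 8 passed without non-responder 2, and 10 medians changed sign with the muscle score as a covariate. edgeR called 0 genes (lowest FDR 0.0779) with 1562 (9.2%) at an unadjusted p below 0.05, DESeq2 called 339, 228 higher and 111 lower, and limma voom 0. The 5 genes with the smallest p, not passing, were Dlx3 (9.86 ± 1.66 to 55.8 ± 12.9 CPM), Tgm3, Cdh13 (−1.06), Srcap (−2.40, overlapping Gm42715) and Neo1 (0.94).

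**Figure D4:**
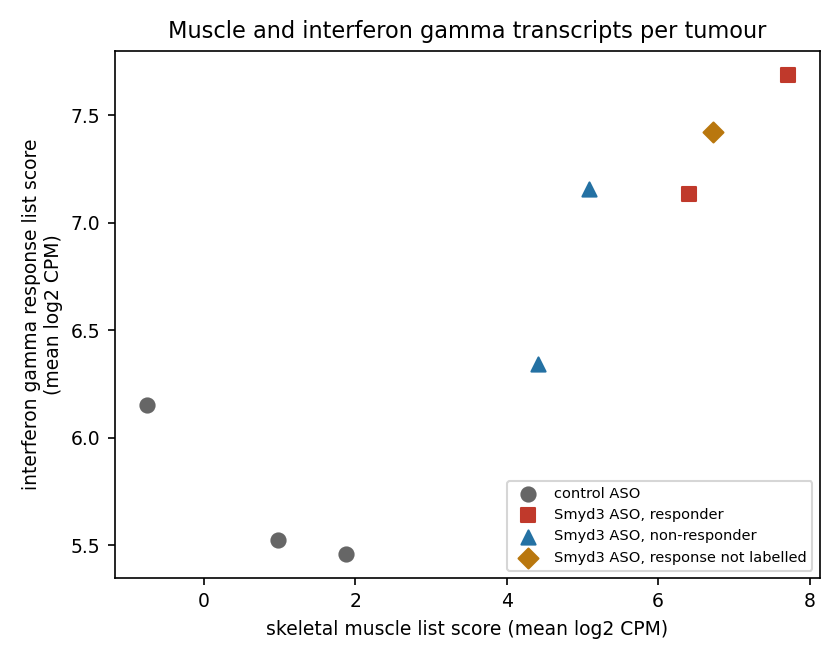
Interferon gamma response score (vertical axis) against skeletal muscle score (horizontal axis), both as mean log2 CPM of the list, 1 point per tumour with symbols for arm and response mark. The controls lie at muscle scores of −0.75 to 1.88 and interferon gamma scores of 5.46 to 6.15, and the 5 Smyd3 ASO tumours at 4.42 to 7.71 and 6.34 to 7.69.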

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

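Of the tests in this part, those of the muscle profile and of interferon gamma against muscle levels were fixed before their results were seen, and those of the T cell against the fibroblast score, of the interferon gamma against the pan-leukocyte score and of Srcap with Gm42715 were chosen after. Within the 5 Smyd3 ASO tumours, 148 list scores and log2 levels of named genes were searched for a tumour whose gap to its nearest neighbour took more than 0.71 of the whole range. Chance gives about 1 in 20, or 7.4, and 9 were found. Non-responder 1 lay apart in 5 of them. It was lowest in the MHC class I score (8.04 against a mean of 8.82 in the others, gap 0.711 of the range), in Tgtp1 (0.717), in Tap1 (0.745) and in Ifih1 (5.33 against 6.27, 0.749), and highest in the DNA methylation and heterochromatin score (6.23 against 5.91, 0.728). Responder 1 was highest in the score of the clock output genes (0.78), a list chosen after the data were seen, and lowest in Sprr3 (0.857). Responder 3 was highest in Ccl4 (3.65 against 2.53, 0.712), and the unlabelled tumour was highest in Dusp4 (6.20 against 5.70, 0.732). Of the 21 lists past the camera threshold between responders and non-responders, 2 had both responders on 1 side of the control mean and both non-responders on the other. This rule used the control mean and not the control range. In terminal keratinocyte differentiation only non-responder 1 lay outside that range (5.65, highest control 4.47), and in the erythrocyte list no Smyd3 ASO tumour did. The terminal keratinocyte differentiation list differed by −1.54 between responders and non-responders and the erythrocyte list by 1.19, and neither passed with an estimated correlation (adjusted p = 0.495 and 0.520), nor the second without responder 1 or non-responder 1.

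The first pattern is the rise of skeletal muscle transcripts in all 5 Smyd3 ASO tumours. A candidate source is host muscle beside the tumour, at the flank by the series design although the source name is a tongue carcinoma, which would bring its transcripts in a single profile. Over the 21 genes of the list, none of which is in another list, the lowest of the 10 correlations between Smyd3 ASO tumours was 0.85 and the highest 0.996, as this source needs, and between controls they were 0.731 to 0.8. Acta1, among the most abundant, was at 14.9 ± 6.05 CPM in controls and 952 ± 1030 CPM in Smyd3 ASO tumours. Controls, with few muscle transcripts, already reached 0.8, so a high correlation does not by itself single out host muscle. An effect of the Smyd3 ASO on muscle genes in host or tumour cells was not tested and stays open.

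The second pattern is the higher level of the interferon gamma list. If it came with the muscle, each tumour's rise in these transcripts would stand in a fixed ratio to its rise in muscle transcripts, but the ratios differed 7.51-fold, from 54.7% in responder 3 to 411% in non-responder 2, which argues against muscle as the whole source. A lower share of tumour cells would raise T cell and fibroblast markers alike, while the T cell minus fibroblast score was higher by 1.62 in the Smyd3 ASO arm. Both lists were already known to differ in these tumours, in opposite directions, so this difference is no independent test. The basal squamous keratinocyte score was below the lowest control in 4 Smyd3 ASO tumours and above the highest in 1. A lower share of tumour cells is therefore not decided here. More leukocytes with unchanged expression would raise the list no more than the pan-leukocyte genes, but the difference of both scores was higher by 1.03, with 5 of 5 tumours above all controls. A stronger interferon gamma response in the tissue may be part of the difference, as a hypothesis. More T cells, a lower share of tumour cells with a changed mix of other tissue, and a different collection of the arms stay open. The T cell list was at 0.003 with the muscle score as a covariate, an extrapolated value that decides nothing here.

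The third pattern is the low level of Srcap. Reads divided differently between Srcap and the overlapping Gm42715 would leave their sum unchanged, but the sum was lower in 5 of 5 Smyd3 ASO tumours than in every control, with a log2 ratio of −0.64. Gm42715 alone was at 200 ± 44.7 CPM in controls and 213 ± 12.9 CPM in Smyd3 ASO tumours. A lower Srcap level in the Smyd3 ASO arm may be real as a hypothesis, and the assignment of reads between its transcripts was not tested.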

How the results depend on the processing

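The choices named here were made before the data were examined, except the skeletal muscle covariate for the lists of all comparisons and for the gene counts and Smyd3 of responders and of non-responders against controls, and the replicate block for the lists, which were added after the data had been seen. Depth limits single genes near the filter, where 0.424 CPM is 10 reads, and the number of tumours limits the contrasts of 2 against 2 and 2 against 3. Where a left-out library leaves 1 tumour in a group, that tumour is assumed to vary like the other groups. The direction of Smyd3 in Smyd3 ASO against control ASO was the same under 12 of 13 settings and without each of the 8 libraries. RLE and upper quartile size factors, a stricter filter and a fold threshold gave 0 genes for Smyd3 ASO against control ASO, responders against non-responders and non-responders against controls, as did limma voom. In responders against controls these gave 293 (280 shared with the 280), 282 (272 shared), 226 and 251 genes. RLE size factors and the stricter filter gave 19 to 24 lists in each comparison.

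DESeq2 called 1053 genes in Smyd3 ASO against control ASO, 225 in responders against non-responders, 1153 in responders against controls (279 shared with the 280) and 339 in non-responders against controls. Without a filter on low counts, the numbers were 52, 7, 499 (220 shared) and 32. limma voom called 77 genes in responders against controls, 72 of them shared, and the fit of only the libraries compared called 171, 137 of them shared. With an estimated correlation 0 lists passed in each of the 4 comparisons, and by fry 1 list passed in Smyd3 ASO against control ASO and 0 in the others. In Smyd3 ASO against control ASO, only the 6 numbered libraries gave 285 genes, the mean of responders and non-responders in the 4-group model 25, voom with sample quality weights 154, and 1 surrogate variable 23. With quality weights Hbb-bt and Hbb-bs were at 0.042 and 0.10. The cause of these shifts was not tested.

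The replicate number was not found to pair the tumours. Deviations of same-numbered controls and Smyd3 ASO tumours from their group means correlated at −0.03, 0.00 and 0.08, and not every tumour correlated best with its own number. With the replicate block, Smyd3 ASO against control ASO gave 292 genes, 247 higher and 45 lower, and responders against controls 299, of which 194 were shared with the 280. The block gave 21 and 20 lists in these comparisons. It ended 1 of the 22 list calls in the first and 2 of the 21 in the second. Hbb-bt and Hbb-bs were at 0.059 and 0.13 in the first.

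The skeletal muscle covariate was higher in all 5 Smyd3 ASO tumours than in all controls, and higher in both responders than in both non-responders. The compared groups do not overlap in it, so the values of this fit are extrapolated and signs that turn with it decide nothing about the cause. The covariate is the score of the skeletal muscle list, so the change in this list's own values is built in. With it 0 genes were called in responders against controls, and 9 lists passed in Smyd3 ASO against control ASO. Smyd3 was at 0.11, 0.45, 0.79 and 0.34 in the 4 comparisons in the order above. Named genes changed sign in 28 of 111 cases in Smyd3 ASO against control ASO, 6 of 112 in responders against non-responders, 31 of 126 in responders against controls and 27 of 106 in non-responders against controls. For the last 2 comparisons only these numbers are given, a limit set after the values had been seen. In Smyd3 ASO against control ASO the interferon gamma list had a median of 0.77 in place of 1.46 and passed camera at the preset correlation (adjusted p = 0.00136), though without the covariate it did not pass with an estimated correlation (adjusted p = 0.452), while the T cell list was at 0.003 (adjusted p = 0.450) and the cytotoxic T and NK cell list at 0.12 (adjusted p = 0.462). In Smyd3 ASO against control ASO the lists that changed sign were type I interferon response −0.43, MHC class I antigen presentation −0.17, B and plasma cell −1.36, mast cell −0.15, basal squamous keratinocyte 0.83, epithelial-mesenchymal transition 0.081, TGF-beta signalling 0.43, hypoxia and glycolysis 0.13, nucleic acid sensing −0.49, skeletal muscle −0.32 and adipocyte −1.30, and the genes included Smyd1 −1.02, Parp14 −0.086, Oasl2 −0.27, Psmb9 −0.10, Cd3d −0.048, Cd3g −0.073, Lag3 −0.16, Jchain −1.08, Mzb1 −1.36, Igkc −1.79, Gata2 −0.90, Col12a1 0.053, Pkp1 0.36, Col17a1 0.60, Krt17 0.32, Dsp 0.48, Snai1 0.34, Ndrg1 0.10, Zbp1 −0.19, Myd88 −0.42, Ifih1 −0.80, Jun 0.071, Plin4 −2.48, Cfd −1.07, Cidec −1.53, Adipoq −3.32 and Sox10 −2.70. In responders against non-responders the lists were type I interferon response −0.27 and adipocyte −0.78, and the genes Ccl21a −0.98, Smad7 0.16, Slc2a1 0.32, Cfd −0.74, Cidec −0.81 and Retn −1.35. In responders against controls the lists were type I interferon response −0.71, fibroblast and matrix 0.41, epithelial-mesenchymal transition 1.29, TGF-beta signalling 0.74, hypoxia and glycolysis 1.17, nucleic acid sensing −0.73, skeletal muscle −0.46 and adipocyte −2.93. In non-responders against controls they were type I interferon response −0.60, MHC class I antigen presentation −0.11, neutrophil −0.95, terminal keratinocyte differentiation −0.15, epithelial-mesenchymal transition 0.77, hypoxia and glycolysis 0.56, inflammatory cytokines −0.12, skeletal muscle −0.26, adipocyte −2.15 and hair follicle −0.36. The cause was not tested.

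Leaving out 1 library at a time gave 0 to 249 genes in Smyd3 ASO against control ASO, with 249 without non-responder 1, 5 without control 1 and 0 without each of the other 6. Responders against non-responders gave 0 to 22, with 22 without responder 1. Responders against controls gave 0 to 298, with 0 without control 1, 6 without control 3, 36 without responder 3, 78 without control 2, 134 without non-responder 2, 171 without non-responder 1, 286 without the unlabelled tumour and 298 without responder 1 (190 shared with the 280). Non-responders against controls gave 0 genes each time and 8 to 25 lists, 8 without non-responder 2 and 25 without non-responder 1. Smyd3 in responders against non-responders ranged from −0.69 to 0.42 and was 0.29 without responder 3. The lowest and highest values of the other results that changed sign were as follows. In Smyd3 ASO against control ASO they were Hbb-bt −0.95 (without control 1) to 0.37 (without control 2), Hbb-bs −0.83 (without control 1) to 0.36 (without control 2), the epithelial-mesenchymal transition list −0.60 (without control 1) to 0.052 (without control 2) and the TGF-beta signalling list −0.35 (without control 3) to 0.05 (without control 2). In responders against non-responders they were Gata2 −0.061 (without responder 3) to 1.81 (without non-responder 2), Cdc20 −1.04 (without non-responder 2) to 0.28 (without non-responder 1), Slc2a1 −1.65 (without non-responder 2) to 0.19 (without non-responder 1), Hells −0.83 (without non-responder 2) to 0.03 (without non-responder 1), the DNA methylation and heterochromatin list −0.33 (without non-responder 2) to 0.013 (without non-responder 1), Krt27 −12.14 (without responder 1) to 1.47 (without non-responder 2), Krt33a −10.90 (without responder 1) to 3.62 (without non-responder 2) and the hair follicle list −10.90 (without responder 1) to 1.47 (without non-responder 2). In responders against controls they were Hba-a1 −0.065 (without control 1) to 1.25 (without control 2), Krt25 −1.91 (without responder 1) to 5.54 (without control 3) and the macrophage and monocyte list −0.052 (without responder 3) to 0.71 (without responder 1). In non-responders against controls they were Top2a −0.009 (without non-responder 1) to 0.86 (without non-responder 2), the proliferation and cell cycle list −0.21 (without non-responder 1) to 0.59 (without non-responder 2), Jchain −0.84 (without non-responder 2) to 4.81 (without control 3), Ms4a2 −0.19 (without non-responder 2) to 2.96 (without non-responder 1), Krt25 −1.91 (without non-responder 2) to 11.18 (without control 3), Krt73 −0.47 (without non-responder 2) to 6.44 (without control 3), Krt33b −5.31 (without non-responder 2) to 7.11 (without control 3) and the hair follicle list −1.91 (without non-responder 2) to 7.24 (without control 3). The cause was not tested.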

Other observations

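The tests of other splits and the list of clock output genes were chosen after the values had been seen, so no test of this list between the arms is given. Its score was part of the search for a tumour lying apart. Its 9 genes had a score of 5.84 ± 0.06 in controls and 5.27 ± 0.114 in Smyd3 ASO tumours. In 5 of them every Smyd3 ASO tumour lay below every control, and none passed the FDR threshold. Dbp went from 52.2 ± 5.44 to 22.3 ± 5.16 CPM and Per3 from 61.3 ± 6.51 to 35.8 ± 5.08 CPM, with FDR of 0.0656 and 0.0811. Nr1d1, Per2 and Tef had log2 fold changes of −0.63, −0.66 and −0.42, and Hlf, Per1 and Nr1d2 of −0.15, −0.16 and −0.25. The 4 genes of the opposite phase, Arntl, Npas2, Clock and Nfil3, had a score of 4.69 ± 0.402 in controls and 4.64 ± 0.137 in Smyd3 ASO tumours.

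The tumour without a response mark had a muscle score of 6.72, an interferon gamma score of 7.42 and a Smyd3 level of 4.58 CPM. Its T cell score was 2.60, where the mean was 1.75 in controls and 3.28 in responders and the non-responders were at 1.92 and 2.74. Its B and plasma cell score was −0.08, where the responders were at 1.85 and 3.11, the non-responders at −0.48 and 1.07 and the controls at −1.15 to −0.04. In the first 2 principal components, which held 41.7% and 17.8% of the variance, it lay at 23.7 and 8.7, nearest to non-responder 2 at 20.4 and 14.9, and the controls lay at −57.4, −63.1 and −40.2 on the first.

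The other splits of the 8 tumours into 3 and 5 were fitted like the real one, 56 in all. For edgeR calls the real number was 0 and the highest other 1, and since 56 of 56 splits must reach 0, this count says nothing about chance. For genes at an unadjusted p below 0.05, 1 of 56 splits, the real one, gave as many as 2630. The highest other was 2487, with controls 1 and 3 and non-responder 1 as the set of 3. Chance would place the real split first in 1 of 56 cases for a single count fixed beforehand. These counts overlap and were chosen after the values had been seen, so chance is not excluded. For DESeq2 calls 1 of 56 splits gave as many as 1053, with 695 as the highest other, and the same limit holds. Neither count can tell the ASO from other differences between the arms, such as muscle. For lists past the camera threshold 7 of 56 splits gave 22 or more, with 26 as the highest other and a median of 16, so chance is not excluded and the preset correlation passes many lists in arbitrary splits.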
